A study of Mus musculus with 15 samples.

How the data were processed

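RNA of quadriceps muscle from 15 mice was sequenced by the authors with 100 bp single-end reads after ribosomal RNA depletion with a stranded kit, per the labels' protocols. Per the submitters' processing notes, the tools included STAR 2.5.2b, featureCounts 1.5.2 and DESeq2 1.11.8, with genome build mm10. The deposited table holds a signal per gene and sample that the authors made by dividing read counts by a size factor per sample, which was deduced from the values. In every column each value was a whole multiple of the smallest one (tolerance 0.001 of a read, 100% of the values), so whole reads were recovered. Recovered totals were 18457663 to 26981745 reads per library. The table held 50686 genes, of which 50376 (99.4%) matched GENCODE M21 (GRCm38, the assembly of mm10) by identifier without version. Coordinates are from that annotation. Whether the authors filtered genes or samples is not stated in the sources used here.

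Samples were grouped by the group label, with 3 per group, and replicate numbers were given in accession order and pair nothing. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 18.0 to 87.3), so no library was counted as a copy. The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2 of the normalized count plus a pseudocount of 1, with all 15 samples in 1 fit, for 13499 genes with a mean of at least 10. Another 37187 genes were not tested. Fold changes are on that scale, which understates the change of low genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within a comparison, for 8 comparisons. As alternatives, edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 (Wald) and limma voom were run on the recovered reads.

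Before the data were examined, 38 gene lists, the tests, the rule for named genes and the alternatives were fixed. Lists with at least 3 measured members (37, all but the sex-linked list) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, beside an estimated correlation and fry. Of the listed symbols 3 matched no gene. The rule named, per comparison with 1 reference group, the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 50 in a group and no overlap of values. Where fewer than 20 passed, list genes with the smallest unadjusted p filled the number as values that did not pass. It always added Ppargc1a, Slc2a4, Cs, Pdk4, Myh7, Myh4, Ucp3 and Dnmt3b, and every list gene that passed. For the 2 difference tests it named genes that passed only, so Bst2 and Fst there were named after their values were seen. As none passed over all genes, the genes named are those of the lists, and members are said to rise or fall only when adjusted over the list alone. That adjustment does not correct for the choice among 37 lists and 8 comparisons. Such counts were recomputed under the alternatives only where at least 3 members of a list passed. Some list genes named lie outside the first 20, such as Isg15, and were named after their values were seen. The values of some list genes are not reported here. Covariances between comparisons were set beside 100 simulations of unchanged groups with each gene's fitted spread.

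On simulated counts for maternal sedentary against control, with the real means and depths over 13499 genes, the fit found 57% of 100 genes changed by a fold of 2 and 81% of 100 changed by a fold of 4. It called 4 unchanged genes beside them and 0 with no change set, and the simulated spread held no liver transcripts or other shared structure. Alternatives were other pseudocounts, filters, scalings and tests, and leaving out each replicate. A covariate for Xist was planned only if the offspring were of both sexes, and was not run. A liver score, the mean log2 value of 38 genes listed after the liver transcripts were seen, and fits without 4 libraries with liver transcripts or without 2 with few detected genes were added later, as was a fit with the first part of the title code as a covariate. A test in which a group kept 1 library assumed that this library varies like the others. The libraries were thinned to 18457663 reads for the comparison of detected genes. Python packages were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.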

Results

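Quadriceps muscle of adult mouse offspring, 10 months old, was profiled by sequencing of ribosomal RNA-depleted total RNA. The parents had eaten normal chow or a 60% high-fat diet for 6 weeks, and the offspring themselves were on chow and sedentary from birth. The 15 libraries fell into 5 groups of 3. In the control group both parents ate chow and the dams were sedentary. In the maternal groups the mother had the high-fat diet and was sedentary or had a running wheel during pregnancy. In the paternal groups the father had the high-fat diet, and the lean dam was sedentary or had a wheel. The series title asks whether exercise in pregnancy prevents the effect of parental obesity on the offspring. The libraries held 18457663 to 26981745 counted reads each. Whether animals of a group shared a litter is not given in the sources used here, so the p-values measure the spread between these samples. The sample titles are codes of unstated meaning, and the first part of the code is shared by the 3 maternal sedentary libraries and maternal exercised replicate 3. A fit with this part as a covariate, chosen after seeing the data, cannot separate either maternal group from controls or the sedentary groups from each other. For exercise in the maternal arm it rests on maternal exercised replicate 3 alone. In the paternal arm it sets paternal exercised replicate 2 alone against paternal sedentary replicates 1 and 2. The difference between these exercise effects rests on the same exercised libraries.

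The libraries differed in features that could affect the comparisons. Maternal exercised libraries held 18457663 to 20139878 reads, fewer than any maternal sedentary (22927662 to 25781465) or control library (23194887 to 24448553). Reads of 38 genes expressed mainly in liver, such as Alb (albumin) and Apoa1 (an apolipoprotein of plasma HDL), stood at 5195 CPM (reads scaled to the library's total) in maternal sedentary replicate 2 and 616 in replicate 3, but 11.1 in replicate 1. They stood at 315 CPM in paternal sedentary replicate 1 and 210 in control replicate 2, and 2.58 to 40.2 in the other 11 libraries. All 4 libraries with liver transcripts come from offspring of sedentary dams. At least 1 read was seen for 17699 genes in control replicate 2 and 17581 in maternal sedentary replicate 3, against 19062 to 20771 genes in the other 13 libraries. Xist, expressed from the inactive X chromosome of females, had 826 to 3578 reads per library, and each of 4 Y-linked genes had at most 5. Myh7, the slow myosin heavy chain, ranged from 3385 to 44445 reads.

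**Figure D1:**
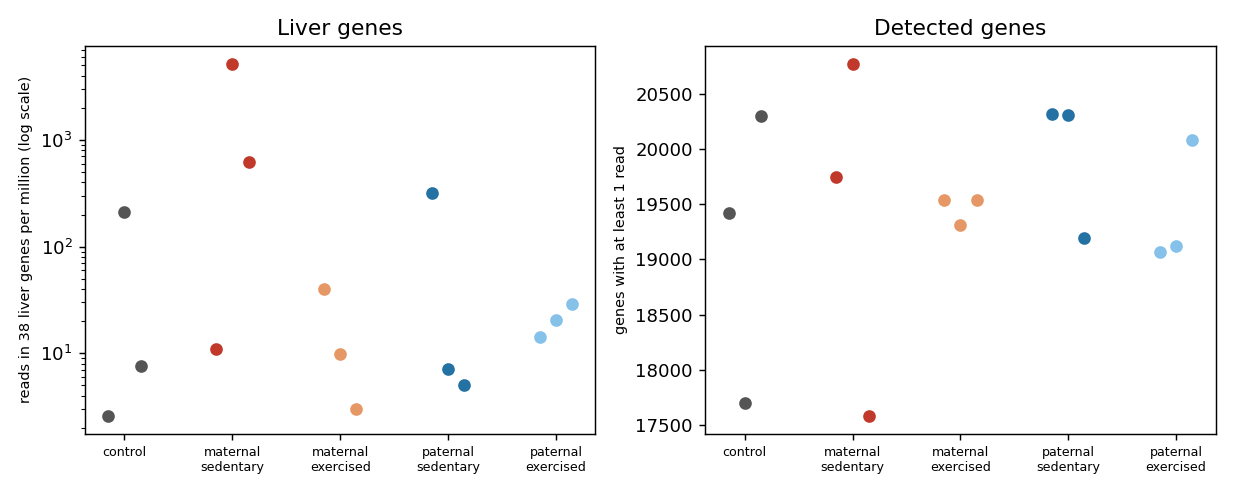
Reads in 38 liver genes as CPM (left, log scale) and genes with at least 1 read (right, axis not starting at 0), with 1 point per library and 3 libraries in each of the 5 groups. Liver genes reach 5195 CPM in 1 maternal sedentary library, and 2 libraries detect 17699 and 17581 genes.

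The first comparison asked how a maternal high-fat diet, without exercise, left its mark on offspring muscle. Genes of interferon response and antigen presentation were higher than in controls. Of 32 measured members of this list, 15 rose when adjusted over the list alone, none fell and 17 did not pass, and 30 of 32 had higher means. Bst2, an interferon-induced membrane protein that tethers virus particles (ENSMUSG00000046718.8, chromosome 8, 71534255 to 71537456, GRCm38), averaged 178 ± 12.1 normalized counts (SD, n = 3) against 92.4 ± 9.62 in controls, a log2 difference of 0.94 ± 0.16 (SE). The guanylate-binding protein Gbp4 (ENSMUSG00000079363.7, chromosome 5, 105115767 to 105139586) averaged 401 ± 207 against 105 ± 21, and the GTPase gene Iigp1 210 ± 91.2 against 54.4 ± 22.4. The peptide transporter gene Tap1 (ENSMUSG00000037321.17, chromosome 17, 34187553 to 34197225) averaged 230 ± 59 against 80.1 ± 32, and the MHC class I heavy chain H2-K1 2999 ± 326 against 1932 ± 203. B2m, Psmb8 and Psmb9, which also serve class I presentation, rose over the list alone by log2 0.66, 0.71 and 1.06. Members that did not pass included Isg15 (log2 0.16 ± 0.43).

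The list's median log2 difference was 0.59, with an adjusted p of 2.63e-25 by limma's camera at a preset correlation of 0.01. The adjusted p was 0.112 with an estimated correlation. Without the 4 libraries with liver transcripts, an alternative chosen after seeing the data, the median was 0.56. The liver transcripts were high in 2 of the 3 maternal sedentary libraries, and Gbp4 was highest in the library with liver genes at 11.1 CPM. Slow fibre genes (14 of 14 with higher means, median 0.54) and fatty acid uptake and oxidation genes (25 of 27, median 0.22) were called higher at the preset correlation, both with an adjusted p of 0.799 with an estimated correlation, and no member passed over the list alone. The slow fibre call ended without control replicate 1 (adjusted p = 0.918) or maternal sedentary replicate 1 (0.309), and the fatty acid call without control replicate 1 (0.104). Macrophage genes were called higher (11 of 13, median 0.64, adjusted p = 0.799 with an estimated correlation), and this call ended without maternal sedentary replicate 2 (0.412) or 3 (0.0578), the libraries with most liver reads. Its direction turned without the 4 libraries with liver transcripts, a fit that keeps only replicate 1 of the maternal sedentary group. Irs1, the insulin receptor substrate, averaged 1218 ± 279 against 577 ± 81.5 and rose over the insulin and AMPK list alone. Over all genes its limma adjusted p was 0.688. Ppargc1a (log2 0.24 ± 0.34), Slc2a4 (-0.01 ± 0.16), Pdk4 (0.19 ± 0.22), Cs (-0.05 ± 0.10), Ucp3 (0.17 ± 0.23), Myh4 (0.04 ± 0.27) and Dnmt3b (-0.10 ± 0.40) did not pass.

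No gene passed an adjusted p of 0.05 over the 13499 genes tested with limma, where 546 had an unadjusted p under 0.05 and chance gives 675. The lowest adjusted p was 0.204. Neither edgeR nor limma voom on recovered reads called a gene (715 and 469 at an unadjusted p under 0.05), and DESeq2 called 18, of which 8 belong to the interferon list.

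**Figure D2:**
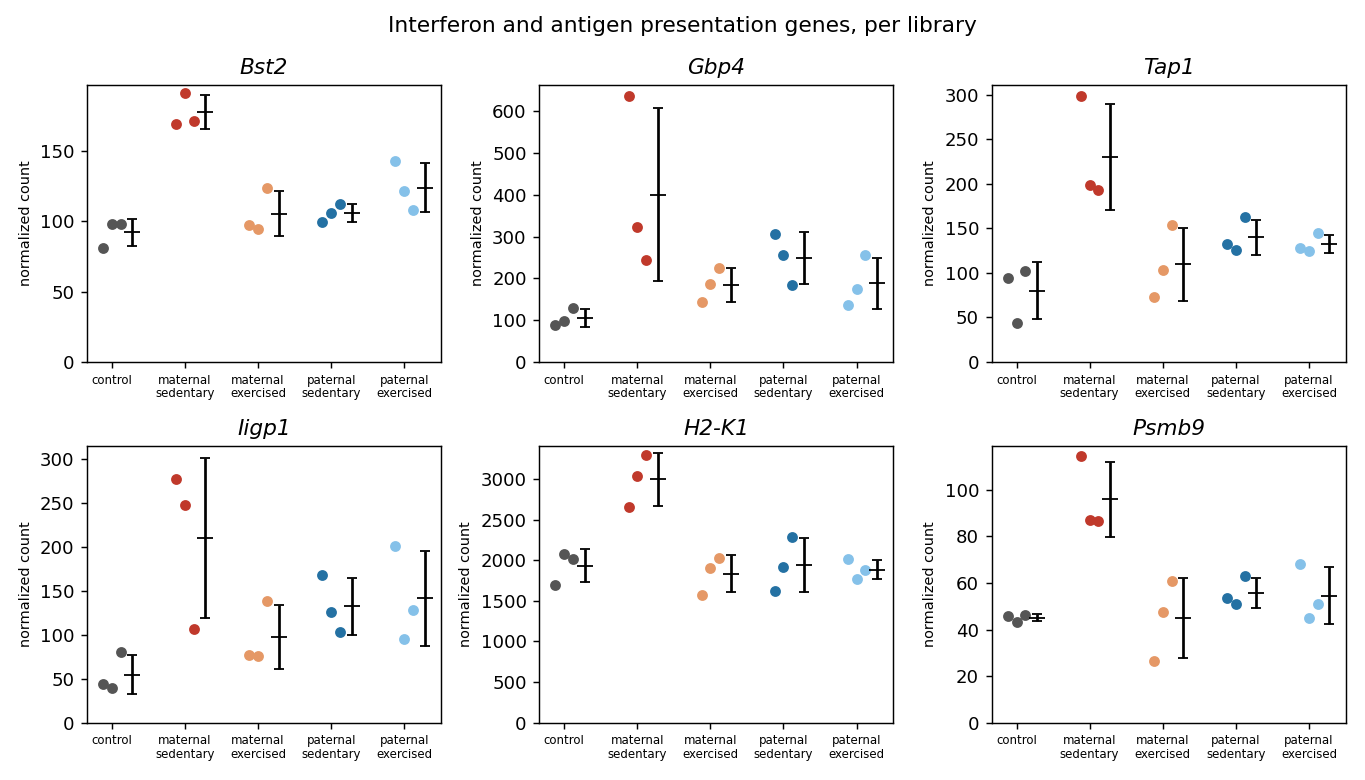
Normalized counts of 6 interferon and antigen presentation genes (linear axes from 0), with 1 point per library and the mean and SD of each group of 3 as a black bar. Maternal sedentary libraries lie above all control libraries in each panel, with Bst2 at 178 ± 12.1 against 92.4 ± 9.62.

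Exercise of the dams was then compared with sedentary dams within the maternal high-fat arm. The same interferon list was lower in offspring of exercised dams, with 13 of 32 members falling over the list alone and 29 of 32 lower on average. The maternal sedentary libraries are those in which the list was high against controls, so this fall and that rise are not independent. H2-K1 averaged 1836 ± 233 against 2999 ± 326 (n = 3), Bst2 105 ± 16.1 against 178 ± 12.1, and Tap1 110 ± 40.8 against 230 ± 59. The median log2 difference was -0.51 (camera adjusted p = 3.1e-10). The adjusted p was 0.731 with an estimated correlation. The number of members passing over the list alone was 3 without maternal exercised replicate 1, 6 without maternal exercised replicate 2 and 5 without maternal sedentary replicate 1. With the title code as a covariate, none passed, the median was -0.18 and the list's call ended (adjusted p = 0.425).

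Of the secreted muscle factors, Mstn (myostatin, an inhibitor of muscle growth) and Fst (follistatin, which binds myostatin) rose over the list alone with exercise, Mstn to 1329 ± 357 from 686 ± 312 and Fst to 62 ± 6.22 from 37.6 ± 8.72. Values of Mstn overlapped between the groups, and both genes had a limma adjusted p of 0.516 over all genes. Complex I genes (28 of 37 lower, median -0.13) and genes of complexes II to V (36 of 42 lower, median -0.18) were called lower as lists, with an adjusted p of 0.731 for both with an estimated correlation, and no member passed alone. Of the mitochondrial genome list only 7 members were tested, and it was called higher (7 of 7, median 0.59, camera adjusted p = 0.0122, and 0.731 with an estimated correlation). That call ended without maternal exercised replicate 1 (adjusted p = 0.0635) or maternal sedentary replicate 3 (0.252), and, in alternatives chosen after seeing the data, without the 4 libraries with liver transcripts (0.669) or the 2 with few detected genes (0.162), with the liver score (0.0816) and with the title code (0.102). The atrophy list, which includes ubiquitin ligase and proteasome genes, was called higher (18 of 21, median 0.29), with the same adjusted p of 0.731. That call ended, at 0.17, without maternal exercised replicate 3.

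limma called no gene over all genes (1288 at an unadjusted p under 0.05), nor did edgeR or voom (1388 and 1040). DESeq2 called 60 genes, of which 54 had their highest value in the maternal sedentary library with the most liver reads. Without maternal sedentary replicate 1, the one of that group with few liver reads, limma called 109.

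The covariance across 13499 genes between the maternal high-fat difference and the exercise difference was -0.247 (r = -0.8). Unchanged groups that share the sedentary libraries gave -0.071 on average over 100 simulations, within -0.086 to -0.061, so the observed value was 0.176 more negative. The simulations drew each gene independently, with the same spread in all groups, so their range does not measure chance where genes vary together. With the liver score as a covariate, chosen after seeing the data, the covariance was -0.067 beside a simulated -0.089, and the excess turned to the other side. Without the 4 libraries with liver transcripts it was -0.071 beside -0.124. In the paternal arm the covariance was -0.015 (r = -0.17) beside a simulated -0.072.

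Offspring of exercised high-fat mothers were also set against controls. Of 13 measured Schwann cell genes all had lower means, 4 fell over the list alone and 9 did not pass. Among them Mbp, myelin basic protein, averaged 789 ± 135 against 1460 ± 648, Pmp22 662 ± 83.7 against 1051 ± 374, and Prx 458 ± 31.1 against 909 ± 446. The list's adjusted p was 9e-07 at the preset correlation and 0.527 with an estimated correlation. Without control replicate 2, one of the libraries with liver transcripts and few detected genes, no member passed, and the median moved from -0.61 to -0.35. None passed either without maternal exercised replicate 2 or 3, and 8 passed without control replicate 1. Atrophy genes were called higher as a list (19 of 21, median 0.49, adjusted p = 0.527 with an estimated correlation). Trim63, a muscle ubiquitin ligase, averaged 74911 ± 38578 against 33554 ± 3041 and did not pass. The interferon list was not called, at a median of 0.23. Scd2, a fatty acid desaturase, averaged 279 ± 16.6 against 496 ± 107 and fell over the lipid synthesis list alone. Over all genes its limma adjusted p was 0.566. limma, edgeR, voom and DESeq2 called no gene over all genes, with 1183, 1176, 1116 and 1256 at an unadjusted p under 0.05.

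The paternal arm asked the same of fathers. In offspring of high-fat fathers and sedentary dams, all 5 measured erythrocyte genes fell over the list alone. Hbb-bs, an adult beta globin, averaged 522 ± 146 against 971 ± 345 (n = 3), Hba-a1, an alpha globin, 229 ± 45.5 against 470 ± 180, and Alas2, the erythroid enzyme of haem synthesis, 36.6 ± 23.1 against 80.1 ± 43.2. Globin genes are near-identical copies, so their separate values are uncertain. The median was -1.09, with an adjusted p of 5.23e-06 at the preset correlation and 0.741 with an estimated correlation. Without any 1 of control replicates 2 and 3 and paternal sedentary replicates 2 and 3, none of the 5 passed, and edgeR passed none of them with all libraries. None passed either with the title code as a covariate (median -0.26), where the list's call ended (adjusted p = 0.831). Slow fibre genes (13 of 14 with higher means, median 0.46, camera adjusted p = 0.0248, and 0.885 with an estimated correlation) and fatty acid uptake and oxidation genes (23 of 27, median 0.19, 8.89e-06 and 0.741) were called higher as lists, as they were in maternal sedentary offspring against the same 3 controls, with no member passing alone. The slow fibre call ended without paternal sedentary replicate 1 (0.0956) or 3 (0.0538), and its direction turned without control replicate 1 (0.768). The fatty acid call ended without control replicate 1 (0.143). With the title code as a covariate both directions turned (0.074 for slow fibre and 0.728 for fatty acid genes), in a fit where these groups share no code and are linked only through the paternal exercised libraries.

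Of the interferon list, Gbp2 (128 ± 14.2 against 59.3 ± 27.3), Gbp4 (249 ± 61.7 against 105 ± 21) and Iigp1 (132 ± 32.5 against 54.4 ± 22.4) rose over the list alone, with a list median of 0.20 and an adjusted p of 0.741 with an estimated correlation. No member of the list passed without control replicate 1 or 2 or without paternal sedentary replicate 1 or 2, and 9 passed without control replicate 3. None passed with the title code as a covariate. The list's call ended, at an adjusted p of 0.0512, without paternal sedentary replicate 3. Ribosomal protein genes were called lower as a list (64 of 77, median -0.14, adjusted p = 0.741 with an estimated correlation). That call ended, at an adjusted p of 0.456, without the 4 libraries with liver transcripts, and at 0.218 with the title code. The Schwann cell list was called lower as well (12 of 13, median -0.54, adjusted p = 0.741 with an estimated correlation, and 0.181 with the title code). In maternal sedentary offspring it was called lower too (10 of 13, median -0.32, adjusted p = 0.799 with an estimated correlation). With all libraries kept, all 4 groups thus lay below the same 3 controls. The paternal sedentary direction turned without the 4 libraries with liver transcripts (camera adjusted p = 0.888). The maternal sedentary call ended without maternal sedentary replicate 1 (adjusted p = 0.332). Its direction turned without control replicate 2 (0.8) or without the 2 libraries with few detected genes (0.958). limma, edgeR, voom and DESeq2 called no gene (387, 378, 415 and 429 at an unadjusted p under 0.05).

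Within the paternal arm, offspring of exercised and sedentary lean dams were compared. The paternal sedentary libraries are those compared with controls above, so opposite changes in both comparisons are not independent. All 5 erythrocyte genes rose over the list alone, with Hbb-bs at 1091 ± 476 against 522 ± 146 and a median of 1.09 (adjusted p = 0.29 with an estimated correlation). None passed without paternal exercised replicate 1 or paternal sedentary replicate 2, nor with the title code as a covariate, where the list's call ended (adjusted p = 0.296). The slow fibre list was called lower at the preset correlation, with lower means in all 14 genes (median -0.89, adjusted p = 0.29 with an estimated correlation), with Myh7 at 18177 ± 12536 against 30341 ± 4679, and none passed alone. Paternal exercised replicate 1 held 3385 reads of Myh7, against 22999 and 27788 in replicates 2 and 3, so this mean rests largely on 1 library. The list's call held with each replicate left out (highest camera adjusted p 0.0189). Genes of complexes II to V had 40 of 42 means lower with a median of -0.14 and the smallest camera p of this comparison (adjusted p = 1.03e-09, and 0.29 with an estimated correlation). Of the 21 atrophy genes 20 had higher means, with Trim63 at 73115 ± 18180 against 35907 ± 18487, which did not pass. Endothelial genes (15 of 16, median -0.13, camera adjusted p = 0.0147, and 0.296 with an estimated correlation), smooth muscle and pericyte genes (10 of 12, median -0.24, 0.00477 and 0.296), macrophage genes (12 of 13, median -0.39, 0.015 and 0.657) and extracellular matrix genes (27 of 33, median -0.28, 0.00477 and 0.698) were called lower as lists, with no member passing alone. The endothelial call ended without paternal exercised replicate 1 (0.202) or 2 (0.0912) or paternal sedentary replicate 3 (0.114), and the smooth muscle call without paternal sedentary replicate 2 (0.0561). The macrophage call ended without paternal exercised replicate 2 (0.0518) or 3 (0.148) or paternal sedentary replicate 3 (0.547), with quantile normalization (0.0921) and with the title code (0.336). The extracellular matrix call ended without paternal exercised replicate 3 (0.209) or paternal sedentary replicate 3 (0.552) and with the title code (0.0624). Mstn averaged 1325 ± 298 against 738 ± 81.6 and did not pass over its list. limma, edgeR and voom called no gene (508, 472 and 475 at an unadjusted p under 0.05) and DESeq2 called 1, Arrdc3. With the title code as a covariate, this comparison sets paternal exercised replicate 2 alone against paternal sedentary replicates 1 and 2. Its title code values thus rest on 1 exercised library, and Trim63 differed there by log2 1.88.

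Offspring of high-fat fathers and exercised dams were set against controls too. Over their lists alone, 5 of 21 atrophy genes rose, among them Foxo1 (log2 1.42 ± 0.46), a transcription factor of muscle atrophy, and Trim63, at 73115 ± 18180 against 33554 ± 3041. Of the antioxidant list 5 genes rose, namely Nfe2l2, Gclc, Gclm, Gsr and Txnrd1, which encode an oxidative stress regulator and enzymes of the glutathione and thioredoxin systems. That list as a whole was not called, at a median of 0.06. Of 12 smooth muscle and pericyte genes 5 fell, with Cspg4, a pericyte surface proteoglycan, at 218 ± 20.1 against 396 ± 116. The Schwann cell genes Mbp, Pmp22 and Prx fell again. The atrophy, smooth muscle and Schwann cell lists were called at the preset correlation, each with an adjusted p of 0.497 with an estimated correlation. The interferon list was also called higher at the preset correlation but not with an estimated one. That interferon call ended without paternal exercised replicate 1 (camera adjusted p = 0.0818). With all libraries kept, the list lay above the same controls in every high-fat group, though it was not called in maternal exercised offspring. Its median was 0.59 in maternal sedentary and 0.20 in paternal sedentary offspring. As the controls are shared, these rises are not independent. Ribosomal protein genes were lower in 72 of 77 cases (median -0.24, camera adjusted p = 2.56e-12, and 0.497 with an estimated correlation), with none passing alone. Single libraries and the tool moved these counts. The atrophy count was 1 with edgeR or voom and 7 with DESeq2. Without control replicate 2 or paternal exercised replicate 2, the number passing was 0 for the atrophy, antioxidant and Schwann cell lists and 1 for smooth muscle. The antioxidant count was also 0 without control replicate 1 or paternal exercised replicate 3, and the Schwann cell count 0 without paternal exercised replicate 1 and 7 without control replicate 1. The atrophy count was 2 without control replicate 1 or paternal exercised replicate 3 and 9 without control replicate 3. The smooth muscle count was 3 without paternal exercised replicate 1 and 8 without control replicate 3. With the title code as a covariate, the counts were 2 for the atrophy and antioxidant lists and 0 for smooth muscle and Schwann cell genes. limma called no gene over all genes (1850 at an unadjusted p under 0.05, where chance gives 675), nor did edgeR or voom (1782 and 1717). DESeq2 called 65, of which 40 were higher and 25 lower.

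**Figure D3:**
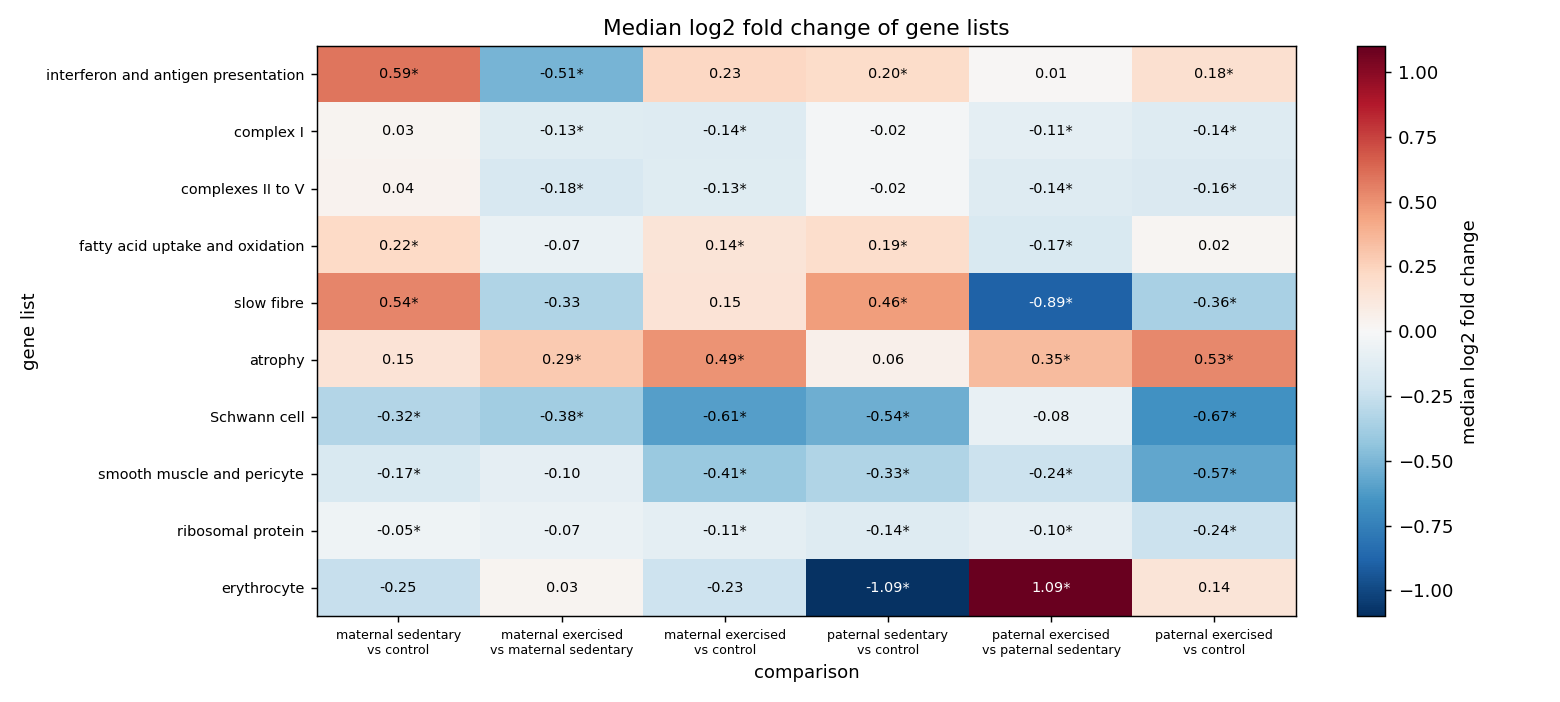
Median log2 fold change of 10 gene lists (rows) in the 6 comparisons (columns), with red for higher and blue for lower in the first-named group, and an asterisk for a camera adjusted p under 0.05 at the preset correlation. The interferon list stands at 0.59 in maternal sedentary against control and at -0.51 with exercise, and none of the calls holds with an estimated correlation.

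The parents' effects were compared directly. Between maternal and paternal sedentary offspring, Bst2 (log2 0.74 ± 0.16) and H2-K1 (0.64 ± 0.14) of the interferon list were higher in the maternal group and passed over the list alone, while no gene passed over all genes with limma, edgeR, voom or DESeq2 (587, 785, 547 and 758 at an unadjusted p under 0.05). The list's median was 0.46 (camera adjusted p = 5.73e-09, and 0.989 with an estimated correlation). In the test of the difference between the exercise effects, Bst2 (log2 -0.97 ± 0.23) and Fst (1.25 ± 0.30) passed over their lists alone. No gene passed over all genes with any of the 4 tools (243 with limma, 264 with edgeR, 214 with voom and 332 with DESeq2 at an unadjusted p under 0.05). The high-fat differences of the arms had a covariance of 0.057 (r = 0.36) across genes. Unchanged groups sharing the 3 controls gave 0.072 on average (0.061 to 0.086 over 100 simulations), so the observed value was 0.015 lower. The sign of this difference turned without control replicate 2 (0.028), paternal sedentary replicate 2 (0.015) or 3 (0.011) or maternal sedentary replicate 3 (0.001), and, in alternatives chosen after seeing the data, with the liver score (0.003) and without the 2 libraries with few detected genes (0.032). The 3 controls are too few to be split between the comparisons. Shared controls alone gave a simulated covariance above the observed one with all libraries, so no effect in common to both parents can be read from it. These simulations also drew each gene independently, so their range does not measure chance where genes vary together.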

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

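The tests of liver RNA as such, of a response of muscle, of liver RNA and of leukocytes in the interferon pattern, of depth, of the top genes and of both median forms for low complexity were chosen after the results were seen. The test of the sex of the liver RNA came from sex-biased genes and Y-linked reads already seen, and used other genes whose values had not been seen.

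Gene lists whose difference between the arms was itself tested stood out. Between the sedentary groups, camera at the preset correlation called the interferon list (adjusted p = 5.73e-09), the erythrocyte list (0.0117) and the mitochondrial genome list (0.0258). Between the exercise effects it called the interferon list (5.54e-11), the erythrocyte, extracellular matrix and imprinted lists (0.00034 each), the tendon list (0.000346), the glycolysis list (0.0042), the slow fibre and secreted factor lists (0.0172 each), the endothelial list (0.0333), and the fast fibre, denervation and ribosomal protein lists (0.0347 each). None held with an estimated correlation (lowest adjusted p 0.321). Of these 15 calls, 11 ended without a single library. Between the sedentary groups, the interferon call held, while the erythrocyte call reached 0.144 without maternal sedentary replicate 2 and the mitochondrial genome call 0.691 without maternal sedentary replicate 3. Between the exercise effects, the interferon, erythrocyte and imprinted calls held. With the title code as a covariate, the interferon direction turned, the erythrocyte call ended and the imprinted call held. On the exercised side that fit rests on maternal exercised replicate 3 and paternal exercised replicate 2 alone, so it decides none of these calls. At the highest, the other lists reached 0.826 (extracellular matrix) and 0.429 (ribosomal protein) without maternal exercised replicate 3, which stands apart in Mmp13 and Cthrc1, 0.496 (fast fibre) and 0.0809 (glycolysis) without maternal exercised replicate 1, 0.417 (denervation) and 0.0873 (tendon) without paternal sedentary replicate 3, 0.174 (endothelial) and 0.85 with the direction turned (slow fibre) without paternal exercised replicate 1, and 0.144 (secreted factor) without paternal sedentary replicate 1.

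Liver transcripts were high in 4 libraries of 3 groups. A response of muscle to maternal high-fat feeding is argued against, since the highest control library had 18.9 times the liver CPM of the lowest maternal sedentary one. RNA of liver in the libraries stays open, because the liver genes were raised together (33 to 38 of 38 above 8 times the median of the other libraries), but the lowest rho between pairs was 0.789 across 38 genes, just short of the 0.8 set. In maternal sedentary replicate 3, 10 male-biased liver genes took 5.12 times the highest share in the other 3 libraries, and 10 female-biased genes took 0.24 times the lowest. As all libraries express Xist, this is consistent with liver RNA from a male animal in that library, a hypothesis that leaves its route unknown.

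The interferon list was higher in maternal sedentary offspring, and less so in the other high-fat groups, against the same controls. Liver RNA as the whole cause is argued against, as the median was 0.65 with the liver score as a covariate (adjusted p = 5.53e-31). The libraries with few detected genes are argued against in the same way, with a median of 0.63 without them. More leukocytes cannot be told apart from a change within the muscle, since the list's median minus that of 17 leukocyte genes was -0.06 ± 0.44 (SE), and the leukocyte median was -0.17 in replicate 1 but 1.15 and 0.9 in replicates 2 and 3, beside interferon medians of 0.68, 0.69 and 0.51. Replicate 1, with few liver reads, thus had the interferon rise without a leukocyte rise, but 1 library does not decide for the group. Maternal diet stays open as the biological explanation. So does whatever the first part of the title code stands for, which all 3 maternal sedentary libraries share and no control does. Maternal exercised replicate 3 shares it too, with H2-K1 at 2029, among the controls (1701 to 2079) and below all maternal sedentary libraries (lowest 2654), but with Bst2 at 123.9 and Tap1 at 153.2 it lay between the highest control (97.98 and 102.4) and the lowest maternal sedentary library (169.5 and 193.4). This 1 library excludes neither the code nor the diet.

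In the 2 libraries with few detected genes, depth is argued against. After thinning, the better of the 2 detected 0.935 times the genes of the lowest of the other 13. A few genes taking most reads is argued against too, as control replicate 1 had 34.91% of reads in its 10 top genes while detecting 19420 genes, though maternal sedentary replicate 3 had more, 35.21%. Low library complexity cannot be told apart from the rest, and 3 forms of its test were computed. A median form scaled by total was computed first, departing from the form set beforehand, and gave up to 6.025 in maternal sedentary replicate 2, where liver reads distort the scaling. The mean form, as set beforehand, was computed next and gave 6.58 and 7.192 in the 2 libraries, below 781.811 in maternal sedentary replicate 2 and 7.825 in maternal exercised replicate 1, so by the form set beforehand low complexity was not seen. The top 1% of genes gave 98.2% and 66.0% of the latter values, against 14.7% and 27.6% in the 2 libraries, so a few genes decided that form. Only with a median form scaled by median ratio, tried last, did both libraries (lower value 2.732) lie above all others (highest 1.419). Apart from these forms, 3.76% of the 4255 low genes had 0 reads in control replicate 2 and 4.35% in maternal sedentary replicate 3, against 0.02% to 0.68% in the other 13. These genes were chosen by their median in the other 13 libraries, and the share restates the few detected genes. It therefore does not decide on the cause.

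Other splits of the samples were run for each comparison. With 10 splits of 6 samples no share under 0.05 is possible. For the genes called, the real limma count was 0, so all splits had to reach it (10 of 10 in each comparison of 2 groups, 100 of 100 drawn for the difference of exercise effects), and this decides nothing. The highest other split called 127 genes for maternal sedentary against control, where control replicate 2 joined maternal sedentary replicates 2 and 3, and 123 between the sedentary groups, where paternal sedentary replicate 1 joined these. Such counts point to a structure of the samples. Both splits set the libraries with liver transcripts on 1 side, the first also both libraries with few detected genes, and which of these the called genes follow was not examined. The highest other split called 39 for the difference of exercise effects, 3 for maternal exercised and 1 for paternal exercised against control, and 0 in the other pairs. For the leading lists, -log10 of the camera p was 26.1 for maternal sedentary against control (highest other 8.08), 11.1 for exercise in the maternal arm (23.7, and 3 of 10 as large), 7.58 for maternal exercised against control (11.1, and 2 of 10), 7.25 for paternal sedentary against control (13.4, and 2 of 10), 10.6 for exercise in the paternal arm (6.18), 13.2 for paternal exercised against control (8.41) and 9.81 between the sedentary groups (5.43). Where no number is given, only the real split, 1 of 10, was as large. Each leading list was picked for its smallest camera p under the real grouping, and the other splits were judged on that same list. The comparison thus favours the real split, and a high rank of it decides nothing. For the difference of exercise effects, 9 of 100 drawn splits gave a list value as large as 11.8 (highest other 23.6), so chance cannot be excluded.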

How the results depend on the processing

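The fits with a liver score or the title code and those without the liver or few-gene libraries were chosen after seeing the data. No paired analysis was possible because the replicate numbers were given in accession order and pair nothing. The first part of the title code, of unknown meaning, is shared between groups, and as a covariate it could be separated in 5 of the 8 comparisons (5 residual degrees of freedom). It gave 16 genes for exercise in the maternal arm, 11 in the paternal arm, 1 for the difference of exercise effects and 0 for either paternal group against control. DESeq2 called 18 genes for maternal sedentary against control, 60 for exercise in the maternal arm, 1 for exercise in the paternal arm and 65 for paternal exercised against control, where limma called 0. The cause was not tested. With each replicate left out, the counts ranged from 0 to 1 for maternal sedentary against control (1 without maternal sedentary replicate 3), 0 to 109 for exercise in the maternal arm (109 without maternal sedentary replicate 1), 0 to 1 for exercise in the paternal arm (1 without paternal sedentary replicate 3) and 0 to 1 for paternal exercised against control (1 without control replicate 3), and were 0 in the other comparisons. All other alternatives called 0.

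The excess covariance of the maternal arm (-0.176) turned to 0.022 with the liver score and to 0.054 without the 4 liver libraries, and ranged from -0.496 to -0.043 with each replicate left out. The paternal one (0.057) ranged from 0.03 to 0.078. That of the high-fat effects (-0.015) turned to 0.003 with the liver score and 0.032 without the 2 few-gene libraries, and ranged from -0.075 to 0.028, with 0.028, 0.015, 0.011 and 0.001 without control replicate 2, paternal sedentary replicates 2 and 3, and maternal sedentary replicate 3.

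Every list call was lost with an estimated correlation and with fry. For the leading lists the adjusted p were 0.112 and 0.0852 (interferon, maternal sedentary against control), 0.731 and 0.262 (interferon, exercise in the maternal arm, also 0.425 with the title code), 0.527 and 0.286 (Schwann cell, maternal exercised against control), 0.741 and 0.856 (ribosomal, paternal sedentary against control, also 0.456 without the liver libraries and 0.218 with the title code), 0.29 and 0.325 (complexes II to V, exercise in the paternal arm), 0.497 and 0.0873 (ribosomal, paternal exercised against control), 0.989 and 0.992 (interferon, between the sedentary groups) and 0.526 and 0.823 (interferon, difference of exercise effects, where the title code turned the direction, 0.872). With each replicate left out, the calls of these leading lists at the preset correlation held, while of the 70 calls of other lists 50 ended without at least 1 of the libraries. The leading lists were picked for the smallest camera p in these same data, so this contrast does not measure their reliability. The interferon genes passing over the list alone ranged from 14 to 18 for maternal sedentary against control and from 3 to 17 for exercise in the maternal arm (0 with the title code). Over the list alone, voom passed 0 interferon genes and edgeR 0 erythrocyte genes for paternal sedentary against control, and fits of only the groups compared passed 0 Schwann cell genes for either exercised group against control. For paternal exercised against control, the atrophy count of 5 was 1 with edgeR, voom or limma's robust fit, 2 with quantile normalization and 10 in a fit of only the groups compared.

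Directions turned, with these adjusted p, for the Schwann cell list against control (0.8 without control replicate 2, in a range from 1.76e-05, and 0.958 without the few-gene libraries in the maternal sedentary comparison, 0.888 without the liver libraries in the paternal one), the macrophage list (0.7) and the mitochondrial genome list between the sedentary groups (0.161) without the liver libraries, and the slow fibre list (0.768 without control replicate 1 in paternal sedentary against control, in a range from 3.6e-05, then 0.666 and 0.85 without paternal exercised replicate 1 in paternal exercised against control and in the difference of exercise effects, in ranges from 2.16e-05 and 0.000105, 0.988 without the liver libraries in the latter). With the title code they turned for slow fibre (0.074), fatty acid (0.728) and smooth muscle genes (0.836) in paternal sedentary against control and slow fibre genes in the difference of exercise effects (0.195). Of 3448 alternative values of named genes 3360 moved by less than 1 SD, 67 by more, 21 passed the threshold and 94 changed sign. A covariate for Xist was not run, as all 15 libraries express it and Y-linked genes had at most 5 reads. Depth limits the genes with few reads, and 37187 genes with a mean under 10 were not tested.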

Other observations

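Of 37 lists tested, 25 were called by camera at the preset correlation in at least 1 comparison and 12 in none. The 12 were the citric acid cycle, PGC-1 network, antioxidant, fibro-adipogenic progenitor, adipocyte, lipid synthesis, lymphocyte and neutrophil, unfolded protein, heat shock, circadian clock, chromatin modifier and nuclear RNA lists, with a lowest adjusted p of 0.068.

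Nlrc5 and Cd274, outside the lists and named after their values were seen, moved with the interferon genes by DESeq2 in maternal sedentary offspring. Nlrc5, a transactivator of MHC class I genes, had a log2 difference of 1.53 (adjusted p = 0.000216) and Cd274, the ligand of the PD-1 receptor, one of 2.02 (adjusted p = 0.000216). Maternal exercised replicate 3 stood apart in a matrix metalloproteinase gene, Mmp13, with 815 reads against at most 17 in the other libraries, and in Cthrc1 with 121 reads.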
